A study of Mus with 4 samples.

How the data were processed

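Gene expression was measured in PPS-ICBR cells, which the labels describe as a mouse prostate cancer cell line, on 4 Affymetrix mouse expression arrays, each hybridised with biotin-labelled material prepared by the manufacturer's standard protocol. Per the labels' protocols, cells were plated at 60% confluency and kept overnight with 5 µM vorinostat in DMSO or with DMSO alone, at 5 µL in 10 mL of medium, and the RNA was column-purified and reverse-transcribed. The labels place 2 arrays in the DMSO group and 2 in the vorinostat group, and the 2 groups share the replicate numbers 1 and 2. Nothing in the labels says whether the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of each value.

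The values are those the authors deposited, on a log2 scale, with 1 value per probe set and array. The submitters' processing notes name RMA and the Transcriptome Analysis Console, with no version. RMA, as it is defined, subtracts background, equalises the intensity distributions of the arrays by quantile normalization and summarises the probes of each probe set in log2 units. Because the distributions are equalised, a change shared by all transcripts cannot be seen in these values. The array medians were 4.19 and 4.22 for DMSO 1 and DMSO 2 and 4.26 and 4.28 for Vorinostat 1 and Vorinostat 2. The genome build behind the probe annotation is not given in the sources used here, and no coordinates are printed.

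The table held 45101 probe sets. The 64 control probe sets were left out of the tests, which left 45037. The platform annotation used for gene names gave 1 symbol to 34945 of these and several symbols to 932, and 9160 were not named here. Identifiers of 34741 probe sets with 1 symbol matched a RefSeq gene table (assembly GRCm38.p6), which updated 0 symbols and was used otherwise only to find which genes neighbour each other. The 18193 genes with 1 symbol were each represented by the probe set with the highest mean over the 4 arrays. Of these, 9010 had more than 1 probe set, and probe sets called in opposite directions occurred in 111 of the 3115 genes with at least 2 called probe sets.

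Vorinostat was compared with DMSO by limma 3.58.1 in R 4.3.3, with a linear model per probe set and moderated variances (lmFit and eBayes, 3.26 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the 45037 probe sets and an adjusted p threshold of 0.05. No low-level filter and no further normalization were applied. A named gene is called near background in a group if on each of its arrays it lies within 1 log2 unit of the highest control for a transcript that was not spiked in, a margin chosen after the data were seen. Such a change is given as at least the difference from that margin. Every log2 change is vorinostat minus DMSO, a difference of means of 2 arrays, followed by its standard error (SE), and every adjusted p of a gene comes from this fit. Gene lists were tested against all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 29 pathway lists. Camera with a correlation estimated from the residuals was an alternative, and in this design of 4 arrays it brought 0 of the 29 lists past the threshold. Its smallest adjusted p was 0.396 and 2 lists had an unadjusted p under 0.05. This alternative rests on the few residual degrees of freedom that 4 arrays leave, so it has little power. It cannot decide whether a list that misses its threshold shifted. Ranges over alternatives of camera leave this one out, as well as fry, which does not compare a list with other genes. Arrays of the 2 groups that do not overlap arise by chance in 33.3% of genes in a design of this size.

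The groups, the tests of the comparison, most of the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The other alternatives and the tests of the closing part came later, as stated beside them. The rule named the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap, whose brighter group lay above the median probe set level and whose names are not predicted or noncoding. It also named, for each list, up to 4 members past the threshold (the 2 largest rises and the 2 largest falls), or the member with the smallest p where fewer than 2 passed. A last part named a set of genes in any case, among them Cdkn1a, Hdac1, Hdac2, Hdac3, Hdac6, B2m, H2-K1, H2-D1, Tap1, Nlrc5, Cd274, Myc and Actb. These parts gave 132 genes, of which 125 passed the threshold. The 29 pathway lists covered cell division, the p53 and BCL2 families, chromatin, ribosomes, antigen presentation and cytokines, metabolism and stress, and epithelial, mesenchymal, neuronal and germline genes. Lists of immune cell, endothelial and fibroblast markers and of reference genes were kept apart from the pathway lists.

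The procedure was tested on simulated data built on the 45037 probe sets of this comparison. With 50 probe sets changed at each of several sizes, 0 of 50 were recovered at 1.25-fold and 0 of 50 at 1.5-fold, against 20 of 50 at 2-fold and 47 of 50 at 4-fold, and 5 unchanged probe sets were called. With 14491 probe sets changed, 83.3% were recovered and 3.44% of the calls were false. Their changes were those of the probe sets that this same fit had called. Small changes that it misses are therefore left out, and the recovery is likely too high. The alternatives covered the variance model, the normalization, the filter on dim probe sets, the choice of probe set per gene, the replicate block, array weights, the threshold, the list test and the omission of each array in turn. In the last, the lone array of a group was assumed to vary like the arrays of the other group. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for reading the table, the closing tests and the figures.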

Results

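RNA from PPS-ICBR cells, a mouse prostate cancer cell line, was profiled on 4 expression arrays after an overnight culture. In 2 of them the cells had received vorinostat at 5 µM, and in the other 2 the solvent DMSO alone. Vorinostat is a hydroxamic acid that inhibits histone deacetylases, the enzymes that take acetyl groups off histones and other proteins. Expression is given as the deposited log2 value, with n = 2 arrays per group.

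The comparison asked which transcripts differed between cells kept with vorinostat and cells kept with its solvent. All 27 mitosis genes and all 29 DNA replication genes measured fell, with a median log2 change of -2.54 and -1.80, and so did 22 of 25 genes on a list of Myc targets and ribosome biogenesis. Each of these 3 lists was called by camera, but had an adjusted p = 0.396 with an estimated correlation. Among the genes that rose were chemokines such as Cxcl1 and Cxcl2, the cell cycle inhibitors Cdkn1a and Cdkn1c and the MHC class I genes H2-K1 and H2-D1. Of 18193 genes, 3806 rose and 3444 fell past the adjusted p threshold of limma, and 10943 did not pass. Changes of at least 2-fold were found in 1044 genes that rose and 1123 that fell, and changes of at least 8-fold in 50 and 21. The 2 DMSO arrays differed by more than 2-fold at 16 probe sets and the 2 vorinostat arrays at 9, against 3734 to 4378 between arrays of different groups. The vorinostat and DMSO arrays did not overlap in 68.9% of genes, where chance gives 33.3%. The counts depended on each array: 2239 genes rose and 2046 fell without DMSO 1, 2261 and 2326 without DMSO 2, 2094 and 2177 without Vorinostat 1, and 2381 and 2312 without Vorinostat 2. On the deposited scale 52.5% of the changed genes were higher, but with each array scaled on 9 reference genes, whose mean change was -0.31, 81.5% were higher (9908 rose and 2245 fell). That scaling raises every log2 change by the same amount and moved the median gene from 0.03 to 0.34, so that falls smaller than this shift become rises under it. The mean of -0.31 rests largely on Gusb (-1.42) and Polr2a (-0.75), and the other 7 reference genes had a mean of -0.09.

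The largest difference in the deposited values was that of Uchl1 (probe set 1448260_at), a ubiquitin hydrolase abundant in neurons, from 3.43 ± 0.01 in DMSO to 9.04 ± 0.21 in vorinostat (SD, n = 2). Its DMSO arrays lay near background, so the rise is given as at least 42.0-fold. Sprr2h, a small proline-rich protein of cornified epithelium, rose by 5.16 (SE 0.08) and the kinase anchor Akap12 by 4.92 (SE 0.15). The Sprr2h probe set (1422240_s_at) is of a type that can match several transcripts, so its value may not be that of Sprr2h alone. The other rises among the 10 largest were those of the adhesion molecule Cadm4 (4.75), the lysosomal glycoprotein Cd68 (4.65), the thioredoxin-interacting protein Txnip (4.47) and the brain-type creatine kinase Ckb (4.44), and of 3 genes near background in DMSO, for which only a lower bound on the log2 scale can be given: the serpin Serpinb1a (at least 4.25, against 1.89 at a second probe set), Rab40b (at least 3.71, against 1.79 at a second probe set) and the retinal dehydrogenase Aldh1a1 (at least 4.35). The order of these 3 and of Uchl1 among the rises is therefore not settled. Other probe sets were looked at after the values were seen: of 68 named genes past the threshold with more than 1 probe set, 15 had another that passed in the same direction but differed by over 1 on the log2 scale, nearer to no change in 14 of them, and 0 had another that passed in the opposite direction. The largest fall was that of Fbxo5 (probe set 1429499_at), an inhibitor of the anaphase-promoting complex, from 9.09 ± 0.01 to 5.33 ± 0.08 (SD, n = 2). It was followed by the replication licensing factor Cdc6 (-3.60, SE 0.18), the kinetochore component Ska1 (-3.55, SE 0.08), the growth factor Artn (-3.52, SE 0.12) and the thymidine kinase Tk1 (-3.50, SE 0.10). Kif2c, Hirip3, Rcbtb2, Mybl2 and Dctd completed the 10, with changes from -3.37 to -3.28. Adjusted p by limma lay between 0.00016 and 0.000183 for the 10 rises and between 0.00016 and 0.000264 for the 10 falls.

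**Figure D1:**
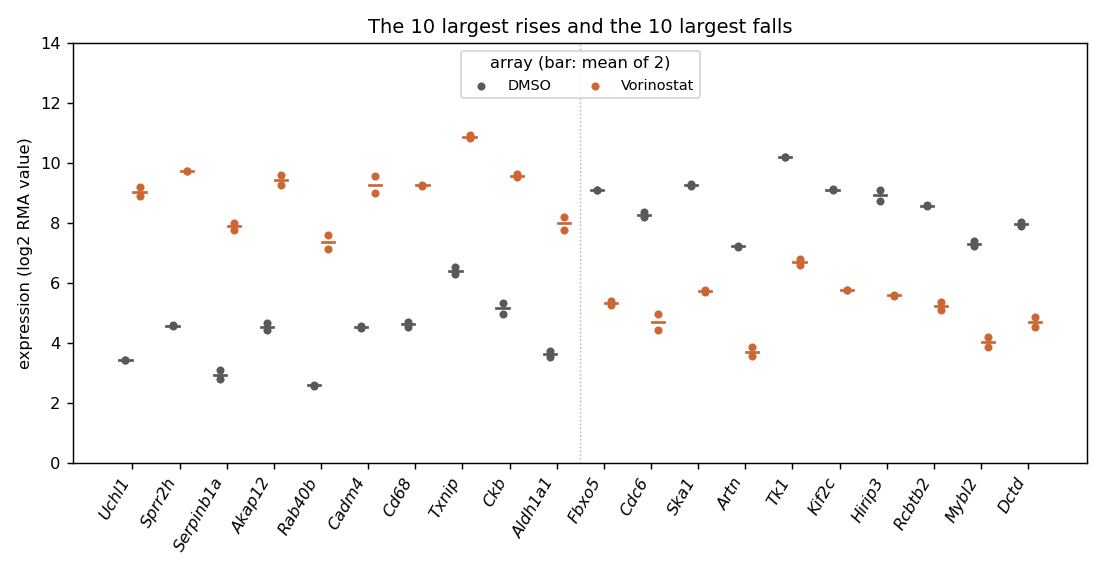
Expression (log2 value, vertical axis) of the 10 genes with the largest rise and the 10 with the largest fall, with 1 point per array, DMSO in grey and vorinostat in orange, and bars at the means of 2 arrays. Uchl1 lies at 3.43 in DMSO and 9.04 in vorinostat, and Fbxo5 at 9.09 and 5.33.

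All 27 measured mitosis genes fell, also when adjusted over the list alone (27), and all of them by at least 2-fold. The kinase Plk1, which drives entry into mitosis, fell by 3.19 (SE 0.15) and the cyclin Ccna2 by 3.15 (SE 0.08) on the log2 scale. All 29 measured DNA replication genes fell, 29 adjusted over the list alone, 24 of them at least 2-fold. Of the homologous recombination and DNA damage response list, 19 of 19 fell, 19 adjusted over the list alone, among them the exonuclease Exo1 (-2.67, SE 0.13). Camera gave an adjusted p of 1.02e-18 for mitosis, 5.41e-18 for DNA replication and 9.46e-11 for homologous recombination, and each had an adjusted p = 0.396 with an estimated correlation. Without DMSO 1, 28 replication and 16 recombination genes passed.

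The list of Myc targets and ribosome biogenesis had 22 of 25 members lower, 22 adjusted over the list alone, with a median of -1.23 (camera adjusted p = 9.43e-11, and adjusted p = 0.396 with an estimated correlation). The spermidine synthase Srm fell by 2.58 (SE 0.08) and the nucleolar factor Utp20 by 2.08 (SE 0.10) on the log2 scale. Myc itself had a change of -0.10 (SE 0.11, adjusted p = 0.576), which became 0.21 under reference-gene scaling. The ornithine decarboxylase Odc1 was the 1 member that rose, by 0.55 (SE 0.09), and it no longer passed without DMSO 1 (0.54), DMSO 2 (0.56) or Vorinostat 1 (0.47). Other, dimmer probe sets of Odc1 rose by 1.41 and 0.41 and passed in the main comparison. Of 16 measured ribosomal protein genes, 4 fell, 4 adjusted over the list alone, including Rps6 (-0.81, SE 0.08) and Rps19 (-0.68, SE 0.08), and the list as a whole did not pass (adjusted p = 0.0538). It passed without DMSO 2 (0.0438, the lowest of a range to 0.0922 over the omission of single arrays) and in 4 of 7 other alternatives of camera, which ranged from 0.00934 to 0.134, though it had an adjusted p = 0.396 with an estimated correlation. Reference-gene scaling gave 6 ribosomal protein genes higher and 3 lower, an intensity trend in the variance 1 and 9, and probe sets above the median level alone 7 lower.

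Among the histone deacetylases, the enzyme family that vorinostat inhibits, 4 of 11 rose and 3 fell, the same numbers (4 and 3) adjusted over the list alone. Hdac11 rose by 1.52 (SE 0.08), Hdac5 by 0.93 (SE 0.09), Hdac6, which deacetylates tubulin, by 0.88 (SE 0.09) and Hdac1 by 0.50 (SE 0.10), while Hdac7 fell by 1.18 (SE 0.15) on the log2 scale. Hdac2 (-0.22, SE 0.09, adjusted p = 0.151) and Hdac3 (0.12, SE 0.08, adjusted p = 0.293) did not pass, and Hdac2 turned to 0.09 under reference-gene scaling. Hdac1 did not pass without DMSO 1 (0.53), DMSO 2 (0.46) or Vorinostat 1 (0.40), and without DMSO 1 none of the 3 falls passed, Hdac7 being at -1.05. The list did not pass as a whole (adjusted p = 0.95), with a median of -0.22 and a mean of 0.03. Of genes known to rise with inhibitors of these enzymes, 10 of 14 rose and 4 did not pass, against 11 that rose adjusted over the list alone (camera adjusted p = 0.000245, and adjusted p = 0.396 with an estimated correlation). Txnip and the chaperone Clu (2.62, SE 0.09) rose most.

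Chromatin writers and readers had 14 of 26 members lower and 3 higher, or 14 and 4 adjusted over the list alone. The acetyltransferase Kat2a fell by 1.75 (SE 0.09) and the maintenance DNA methyltransferase Dnmt1 by 1.67 (SE 0.09) on the log2 scale, while the H3K4 demethylase Kdm5b rose by 1.66 (SE 0.08) and the methyltransferase Ezh1 by 0.77 (SE 0.08). Other, dimmer probe sets of Kat2a were at -1.79 and -0.38, and those of Kdm5b, also dimmer, at 0.71, 0.01 and -0.02. The list passed narrowly (camera adjusted p = 0.0476, and adjusted p = 0.396 with an estimated correlation). The call was lost without DMSO 1 (adjusted p = 0.0922, with 9 members lower) and without Vorinostat 2 (0.067), over a range of 0.0362 to 0.0922 for the omission of single arrays, and in 4 of 7 other alternatives of camera, which ranged from 0.0235 to 0.0929. With arrays scaled on the reference genes, 10 members were higher and 11 lower, and 5 were higher among probe sets above the median level. Of 13 histone genes, 4 rose and 4 fell, 4 and 4 adjusted over the list alone. H2bc21 (1.44, SE 0.09) and the linker histone H1f2 (0.93, SE 0.08) rose, and the centromeric histone Cenpa (-2.56, SE 0.08) and H2ax (-1.94, SE 0.08) fell, with no shift of the list past the threshold (adjusted p = 0.76), and 6 were higher and 4 lower under reference-gene scaling.

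Inhibitors of cyclin-dependent kinases and p53 targets rose in 12 of 18 members and fell in 1, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.00329, and adjusted p = 0.396 with an estimated correlation). Cdkn1a, which encodes p21, rose by 1.69 (SE 0.16), Cdkn1c, which encodes p57, by 3.43 (SE 0.28) and the p53-induced Trp53inp1 by 3.26 (SE 0.14). A second, dimmer probe set of Trp53inp1 rose by only 0.42. The nuclease Aen was the member that fell (-1.18, SE 0.09), and 2 fell with an intensity trend or among probe sets above the median level. Of 21 BCL2 family members and caspases, 7 rose and 7 fell, or 8 and 7 adjusted over the list alone. The pro-apoptotic BH3-only genes Pmaip1 (2.73, SE 0.08) and Bcl2l11 (1.85, SE 0.15) rose, and the effectors Bak1 (-1.30, SE 0.13) and Bok (-1.23, SE 0.08) fell. This list did not shift as a whole (adjusted p = 0.876), and its median was -0.05 and its mean 0.09. Only 3, 4, 3 and 2 of its members rose without DMSO 1, DMSO 2, Vorinostat 1 and Vorinostat 2, and 4 fell without DMSO 1.

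Of 17 measured genes of MHC class I antigen presentation, 11 rose and 4 fell, or 12 and 4 adjusted over the list alone, with a median of 0.68. The class I heavy chain genes H2-K1 (1.56, SE 0.08) and H2-D1 (1.60, SE 0.08), their light chain B2m (0.72, SE 0.09), the class I activator Nlrc5 (1.02, SE 0.11) and the class Ib gene H2-M3 (2.14, SE 0.15) rose. The peptide-trimming enzyme Erap1 (-2.10, SE 0.12) and the immunoproteasome subunit Psmb10 (-1.82, SE 0.10) fell. The peptide transporter Tap1 changed by 0.52 (SE 0.16) and did not pass (adjusted p = 0.0566), although it did in some alternatives. The list as a whole did not pass (adjusted p = 0.0538). It passed without Vorinostat 1 (0.0362, the lowest of a range to 0.0948 over the omission of single arrays) and in 4 of 7 other alternatives of camera, which ranged from 0.022 to 0.0929, though it had an adjusted p = 0.396 with an estimated correlation. Because class I heavy chain genes are near-identical in parts, probe sets for H2-K1 and H2-D1 may hybridise to both, and these values are uncertain as to which gene they measure. Of 10 MHC class II genes, 3 rose, 3 adjusted over the list alone, including the peptide-exchange chain H2-DMa (1.95, SE 0.16) and the invariant chain Cd74 (1.80, SE 0.12), with no shift of the list past the threshold (adjusted p = 0.299), and 6 rose under reference-gene scaling.

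Cytokines and chemokines had 16 of 28 members higher and 6 lower, 16 and 6 adjusted over the list alone (camera adjusted p = 0.00329, and adjusted p = 0.448 with an estimated correlation). The neutrophil attractants Cxcl2 (3.61, SE 0.10) and Cxcl1 (3.37, SE 0.08) rose most, and the CSF1 receptor ligand Il34 fell by 1.00 (SE 0.13) on the log2 scale, the most of the list. Without DMSO 1, DMSO 2, Vorinostat 1 and Vorinostat 2, the members that fell numbered 0, 1, 1 and 3, and Il34 did not pass without DMSO 1 (-0.90). Scaling on the reference genes left 1 cytokine lower and 19 higher. Other probe sets of Cxcl1, looked at after its value was seen, rose by 2.91 and 0.67. Of 40 interferon-stimulated genes, 22 rose and 8 fell, or 23 and 8 adjusted over the list alone (camera adjusted p = 0.0243, and adjusted p = 0.469 with an estimated correlation). The T-cell attractants Cxcl9 (by at least 3.36, from near background in DMSO, against 0.74 at a second and dimmer probe set) and Cxcl10 (2.57, SE 0.11) rose, whereas the antiviral effectors Ifit1 (by at least 1.60, to near background with vorinostat) and Ifit2 (-1.97, SE 0.09) fell. The call of this list was lost without Vorinostat 2 (adjusted p = 0.074, the highest of a range from 0.0075 over the omission of single arrays), and when only genes above the median level were tested (0.0715, the highest of a range from 0.00677 over 7 other alternatives of camera). Its members that fell numbered 3, 4, 5 and 5 without DMSO 1, DMSO 2, Vorinostat 1 and Vorinostat 2, and 5 under reference-gene scaling, where 28 rose. Cytokines also lost their call with only genes above the median level (0.0648, the highest of a range from 0.000681).

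Of 22 immune ligands of tumour cells, 8 rose and 3 fell, or 9 and 3 adjusted over the list alone, without a shift of the list past the threshold (adjusted p = 0.162). The adhesion receptor Nectin2 (2.32, SE 0.15, against 1.23 at a second probe set) and the death receptor Fas (by at least 1.35, from near background in DMSO) rose. The NKG2D ligand Ulbp1 fell (-0.89, SE 0.08). Cd274, which encodes the checkpoint ligand PD-L1, changed by 0.07 (SE 0.11, adjusted p = 0.665) and turned to -0.05 without Vorinostat 2. Without DMSO 1, Vorinostat 1 or Vorinostat 2, 5 members rose and 1 fell, and 2 fell without DMSO 2. Reference-gene scaling gave 15 higher and 2 lower.

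Cholesterol biosynthesis genes rose in 10 of 20 cases and the other 10 did not pass, against 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0318, and adjusted p = 0.448 with an estimated correlation). The sterol reductase Tm7sf2 (2.20, SE 0.09) and the ketosteroid reductase Hsd17b7 (1.75, SE 0.08) rose most. The call was lost without DMSO 2 (adjusted p = 0.057) and without Vorinostat 2 (0.0722), over a range from 0.0114 for the omission of single arrays, and with genes above the median level only (0.0648, the highest of a range from 0.0088 over 7 other alternatives of camera). Only 5 members rose without DMSO 1, without DMSO 2 or without Vorinostat 2, against 15 under reference-gene scaling, and 2 fell with an intensity trend and 1 among probe sets above the median level. Glycolysis genes rose in 4 of 13 cases and fell in 2, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.561). Of the phosphofructokinase genes, the platelet type Pfkp rose by 3.68 (SE 0.12) and the liver type Pfkl fell (-1.70, SE 0.08), and the glucose transporter Slc2a1 rose by 1.05 (SE 0.09) and the lactate dehydrogenase Ldha fell (-0.98, SE 0.09). Without DMSO 1, Vorinostat 1 or Vorinostat 2, 2 glycolysis genes rose, against 9 under reference-gene scaling. Of 22 oxidative phosphorylation genes, 8 rose and 3 fell, 8 and 3 adjusted over the list alone (camera adjusted p = 0.293), with the complex I subunits Ndufb3 (0.86, SE 0.08) and Ndufv1 (0.82, SE 0.10) highest. Their number fell to 3, 3, 3 and 4 without DMSO 1, DMSO 2, Vorinostat 1 and Vorinostat 2, in each case with 0 lower, and reference-gene scaling gave 17 higher and 0 lower.

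Of 20 genes of the unfolded protein and ATF4 response, 6 rose and 7 fell, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.76). The stress-induced factor Atf3 rose by 4.24 (SE 0.14) and the mTORC1 inhibitor Ddit4 by 1.33 (SE 0.09), while the serine synthesis enzyme Psat1 (-1.56, SE 0.08) and the degradation factor Herpud1 (-1.27, SE 0.08) fell. Of 13 heat shock genes, 3 rose and 6 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.747). The small chaperone Hspb1 (2.66, SE 0.08) and the inducible Hspa1a (2.18, SE 0.10) rose, and the collagen chaperone Serpinh1 (-1.87, SE 0.11) and the mitochondrial Hspd1 (-0.91, SE 0.08) fell. Of 13 oxidative stress and metallothionein genes, 7 rose and 4 fell, 7 and 4 adjusted over the list alone (camera adjusted p = 0.195), the glutathione transferases Gsta4 (3.76, SE 0.10) and Gstm1 (1.95, SE 0.08) rising most. The medians of the unfolded protein and heat shock lists were -0.05 and -0.02 and their means 0.12 and 0.14, and under reference-gene scaling more of their members rose than fell, 10 against 6 and 7 against 3, and 5 heat shock genes rose with an intensity trend. Without DMSO 1, 4 unfolded protein genes fell and 4 oxidative stress genes rose, and the oxidative stress genes that fell numbered 0, 1, 1 and 0 without DMSO 1, DMSO 2, Vorinostat 1 and Vorinostat 2, and 0 under reference-gene scaling.

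Genes of cell identity changed in both directions. Of 20 genes of epithelial junctions and simple keratins, 4 rose and 6 fell, or 4 and 9 adjusted over the list alone (camera adjusted p = 0.441). The epithelial factor Elf3 (1.17, SE 0.08) and the keratin Krt19 (1.10, SE 0.10) rose, and the keratin Krt8 (-1.05, SE 0.12) and the splicing regulator Esrp1 (-0.83, SE 0.09) fell. Of 23 mesenchymal genes, 6 rose and 9 fell, or 8 and 9 adjusted over the list alone (camera adjusted p = 0.441), with the hyaluronan receptor Cd44 (1.00, SE 0.11) higher and the smooth muscle actin Acta2 (-1.61, SE 0.08) and the membrane-type protease Mmp14 (-1.42, SE 0.11) lower. Of 16 YAP and TGF-beta targets, 4 rose and 5 fell, or 6 and 7 adjusted over the list alone (camera adjusted p = 0.617). Ccn2 (2.07, SE 0.08) and Ccn1 (1.38, SE 0.12) rose, and Tgfbi (-1.27, SE 0.09) fell. Under reference-gene scaling rises outnumbered falls in these 3 lists, 6 to 3 in the epithelial, 10 to 7 in the mesenchymal and 6 to 3 in the YAP and TGF-beta list. Of the epithelial genes, 3, 2 and 2 fell without DMSO 1, DMSO 2 and Vorinostat 1. Of the mesenchymal genes, 2 rose and 4 fell without DMSO 1, 2 and 5 without DMSO 2, and 4 rose without Vorinostat 2. Of the YAP and TGF-beta targets, 2, 2, 3 and 3 fell without DMSO 1, DMSO 2, Vorinostat 1 and Vorinostat 2.

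Luminal prostate and androgen response genes rose in 5 of 15 cases and fell in 3, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.529). The stress-responsive Ndrg1 (2.30, SE 0.08) and the prostate stem cell antigen Psca (1.32, SE 0.12) rose, and the pioneer factor Foxa1 (-0.96, SE 0.09) and Cd24a (-0.77, SE 0.09) fell, and 8 members rose and 2 fell under reference-gene scaling. Of 11 basal prostate genes, 2 rose, among them the laminin chain Lamb3 (0.88, SE 0.10), and the keratin Krt6a fell (-0.42, SE 0.12), against 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.95). With DMSO 1, DMSO 2, Vorinostat 1 or Vorinostat 2 left out, 1 basal gene rose, and Krt6a did not pass without DMSO 2 (-0.28), Vorinostat 1 (-0.40) or Vorinostat 2 (-0.43). A second probe set of Krt6a, at nearly the same mean level (5.98 against 6.11) and looked at after its value was seen, fell by 2.38 (SE 0.15, adjusted p = 0.00039) on the log2 scale. With arrays scaled on the reference genes, 6 basal genes rose and 0 fell. Neuronal and neuroendocrine genes rose in 9 of 26 cases and fell in 1, 9 and 1 adjusted over the list alone (camera adjusted p = 0.0678). The list passed without DMSO 2 (0.039) and without Vorinostat 1 (0.0294), over a range to 0.208 for the omission of single arrays, and in 2 of 7 other alternatives of camera, which ranged from 0.0128 to 0.116, though it had an adjusted p = 0.396 with an estimated correlation. Reference-gene scaling gave 17 members higher and 1 lower. Besides Uchl1, the secreted neuropeptide precursor Vgf rose by 3.07 (SE 0.29), and the stem cell factor Sox2 fell (-1.44, SE 0.08). Of 19 germline genes 4 rose, against 1 adjusted over the list alone (camera adjusted p = 0.76), with the testis bromodomain gene Brdt at 1.59 (SE 0.16). Dimmer probe sets of Brdt were at -0.16 and 0.19 and did not pass. Of the 19 genes, 16 lay under the median probe set level. Ddx4, among those that rose, was near background in both groups. The germline genes that rose numbered 2, 1, 1 and 1 without DMSO 1, DMSO 2, Vorinostat 1 and Vorinostat 2, and 9 under reference-gene scaling, 2 with repeated quantile normalization and 1 among probe sets above the median level, with 1 lower in each of the last 2.

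**Figure D2:**
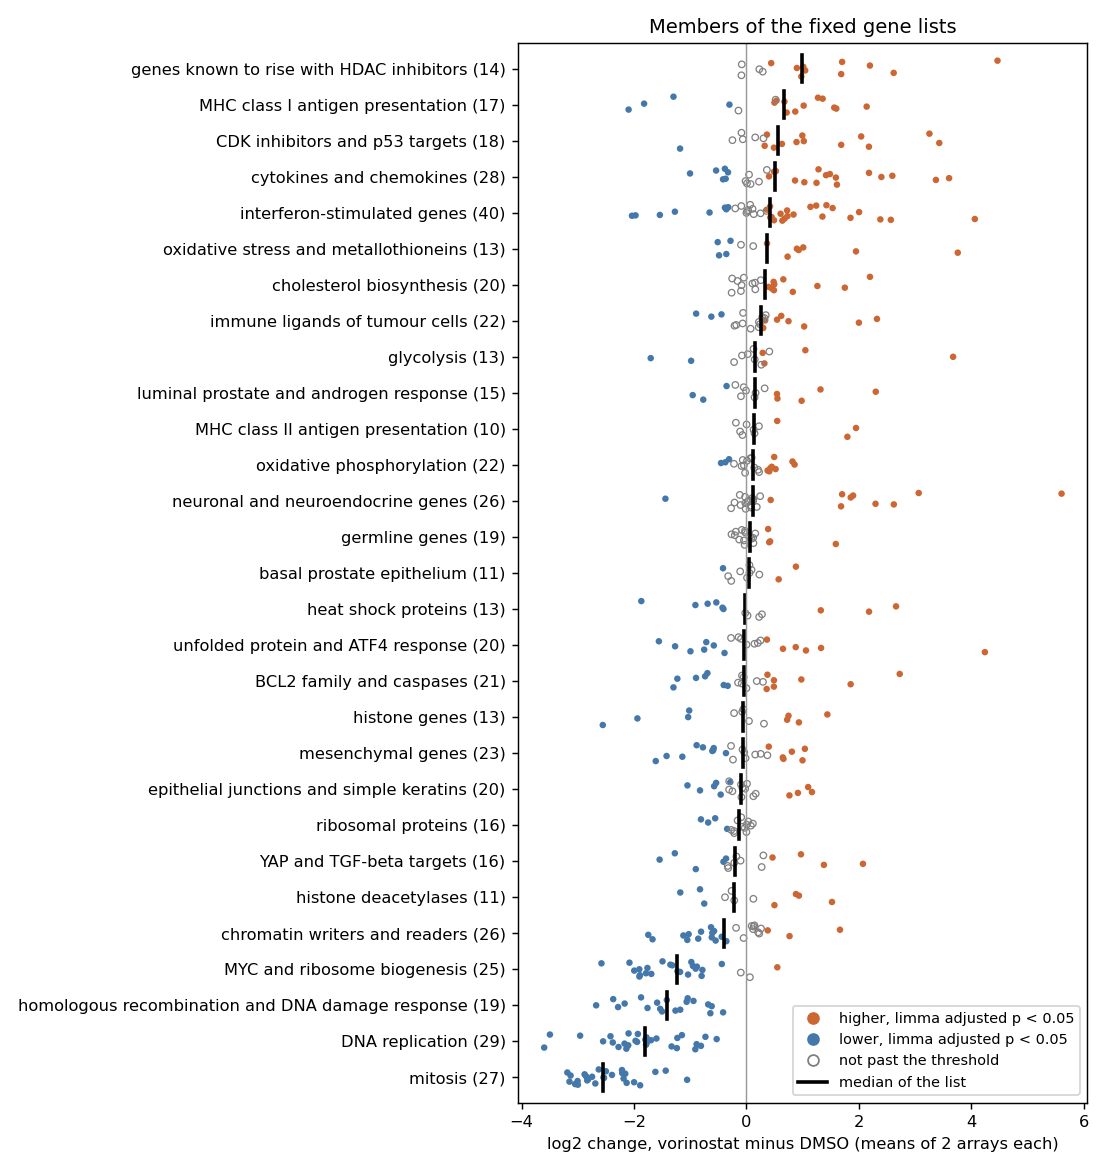
Log2 change (vorinostat minus DMSO, horizontal axis) of each measured member of the 29 pathway lists, with 1 point per gene, the number of measured genes in brackets and a bar at the median. Filled points passed limma's threshold, higher in orange and lower in blue, and open points did not, and the medians run from -2.54 for mitosis to 0.99 for genes known to rise with inhibitors of histone deacetylases, with reference-gene scaling adding 0.31 to every point.

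Markers of cells that the culture was not meant to hold were mostly flat or mixed in their changes. Their median level over the 4 arrays was 3.75 for immune, 2.69 for endothelial and 7.84 for fibroblast markers. Under the median probe set level lay 8 of 12 immune, 7 of 9 endothelial and only 1 of 9 fibroblast markers. Most fibroblast markers were thus expressed in these cultures, and which cells express them was not tested. Of 12 immune cell markers, 2 rose, 2 adjusted over the list alone, namely Cd68 and the T-cell receptor chain Cd3e (0.43, SE 0.09), which did not pass without DMSO 1 (0.37), Vorinostat 1 (0.41) or Vorinostat 2 (0.46). Under reference-gene scaling 5 immune and 2 endothelial markers rose. Of 9 endothelial markers 0 passed in limma, 0 adjusted over the list alone, although 2 had an unadjusted p under 0.05, with Emcn the lowest in p (-0.42, SE 0.12, adjusted p = 0.0565), near background in both groups. Repeated quantile normalization gave 2 endothelial markers lower, an intensity trend 1 and the replicate block 1. Of 9 fibroblast markers, 2 rose and 3 fell, or 2 and 4 adjusted over the list alone. The growth factor receptor Pdgfra (1.54, SE 0.09) and the proteoglycan Dcn (1.26, SE 0.10) rose and the receptor Pdgfrb fell (-2.49, SE 0.10), and 2, 1, 3 and 4 fibroblast markers fell without DMSO 1, DMSO 2, Vorinostat 1 and Vorinostat 2, and 5 with an intensity trend. Of 9 reference genes, 2 fell, 2 adjusted over the list alone, but 5 with an intensity trend and 5 among probe sets above the median level. These were the lysosomal Gusb (-1.42, SE 0.08) and the RNA polymerase subunit Polr2a (-0.75, SE 0.12), which did not pass without Vorinostat 1 (-0.72) or Vorinostat 2 (-0.78). The other 7 reference genes lay between -0.26 and 0.08, with a mean of -0.09, and Actb changed by 0.08 (SE 0.08, adjusted p = 0.511), or -0.02 when quantile normalization was repeated. Reference-gene scaling, which sets their mean to no change, gave 4 of them higher and 2 lower.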

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

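These values lie outside the named genes that the report compares. They were picked after the table had been seen, and no explanation was tested for them. Among the probe sets with no symbol or several symbols, 783 were higher and 716 lower with vorinostat in the same limma fit, and 124 and 144 of them by at least 2-fold, so that part of the response lies in transcripts not named here. A control probe set for the 3′ end of pyruvate carboxylase, an endogenous mouse transcript that is not used in the tests, was higher by 2.09 on the log2 scale, from 6.17 ± 0.10 in DMSO to 8.25 ± 0.0046 in vorinostat (SD, n = 2). The other control probe sets for this transcript rose less, by 0.91, 0.86 and 1.71. The gene's own probe set, Pcx, rose by 2.20 (SE 0.09, limma adjusted p = 0.000183). The control for the 3′ end of the transferrin receptor was lower, at -1.11, and its gene Tfrc fell as well (-0.94, SE 0.08, limma adjusted p = 0.000786).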

How the results depend on the processing

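The comparison of the list medians with random matched lists and the restriction to unique probe sets were chosen after seeing the data, and the other alternatives were planned. Of the named genes, 125 passed the threshold and 0 of these changed direction under any alternative, but 19 did not pass with at least 1 array left out and 46 did not pass without moderation of the variance. Over 1974 alternative values of the 132 named genes, 1842 kept their direction and their side of the threshold, 112 fell short of it, 16 came to pass it and 4 changed sign. Those 4 were Hdac2 (0.0939) and Myc (0.2106) with arrays centred on the reference genes, Actb (-0.0182) with repeated quantile normalization, and the log2 change of Cd274, which ran from -0.0481 without Vorinostat 2 to 0.1977 without Vorinostat 1; none passed in the main comparison. Without moderation, 1506 genes rose and 1599 fell, 648 of the rises at least 2-fold, since each variance then rests on 2 degrees of freedom. With arrays centred on the reference genes, 9908 rose and 2245 fell, 1883 and 651 at least 2-fold, because this adds 0.31 to every change. At an adjusted p threshold of 0.01, 2509 rose. With single arrays left out, 2094 to 2381 genes rose and 2046 to 2326 fell, with fewer samples in each fit. The number of lists shifted higher was 5, against 0 with an estimated correlation (0 lower as well, where the main test had 5), 14 by fry, which asks only whether a list moves on balance, 3 with genes above the median level only, and 3 to 7 with single arrays left out. Why the call of single lists moved with these settings was not tested. Random matched lists placed 6 lists higher and 5 lower. Cholesterol biosynthesis, called by camera, lay within its random range (median 0.3243 against an upper limit of 0.3308). MHC class I (0.6766 against 0.3279) and immune ligands (0.2606 against 0.1909), not called by camera, lay above theirs. On unique probe sets 2875 genes rose and 2506 fell. The replicate numbers were not shown to pair the arrays: the deviations of arrays that share a number correlated at -0.0596 over 45037 probe sets, with only 2 pairs. With the replicate number as a block, 3103 genes rose and 2892 fell, and 5952 of these 5995 genes were shared with the unblocked test, all in the same direction. With the block the chromatin list did not pass (adjusted p = 0.0727, within 0.0235 to 0.0929 over 7 alternatives of camera), nor did 3 named genes that passed without it, and 2 others came to pass. In simulated data 0 of 50 probe sets were recovered at 1.5-fold with few others changed. With 14491 changed by amounts taken from called probe sets, which leaves out small changes, 83.3% were recovered.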

Other observations

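The gene families, the test of immune cell markers and the test of spike-in controls were chosen after the results had been seen, and the tests of neighbouring genes were set before theirs. Families were formed from symbols with a shared stem and at least 10 measured genes, and by camera 6 of 239 families shifted higher and 15 lower, although 0 did so with an estimated correlation, where the smallest adjusted p was 0.97 and 0 families had an unadjusted p under 0.05. With 4 arrays that version has little power, so it cannot decide whether a family shifted. Genes of intraflagellar transport, which carry cargo along cilia, rose in 11 of 14 cases and fell in 1 (adjusted p = 0.0118; adjusted p of at least 0.97 with an estimated correlation), led by Ift22 (1.82) and Ift20 (1.71). With DMSO 1, DMSO 2, Vorinostat 1 and Vorinostat 2 left out, 7, 8, 7 and 8 of them rose and 0 fell. Subunits and partners of the vacuolar proton pump (symbols starting with Atp6) had no test of their own and rose in 11 of 22 cases. They were picked out of the wider Atp family, where 28 of 77 genes rose and 6 fell (adjusted p = 0.0165, and adjusted p of at least 0.97 with an estimated correlation). The subset had a median of 0.37 and Atp6v0a1 at 1.40 (SE 0.09, and 0.24 to 1.10 at its 3 other probe sets), and 7 rose without Vorinostat 1. Matrix metalloproteinases rose in 7 of 18 cases and fell in 1 (adjusted p = 0.0264, and adjusted p of at least 0.97 with an estimated correlation), among them Mmp12 (by at least 3.18, from near background in DMSO) and Mmp3 (1.82, SE 0.08), and 4 rose without DMSO 1 or without DMSO 2. Krüppel-like factors rose in 6 of 16 cases and fell in 1 (adjusted p = 0.0494, and adjusted p of at least 0.97 with an estimated correlation), among them Klf12 (by at least 2.93, from near background in DMSO, but 0.06 to 1.82 at its 4 other probe sets) and Klf2 (1.88, SE 0.14), and none fell without DMSO 1, DMSO 2, Vorinostat 1 or Vorinostat 2.

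Nucleoporins fell in 15 of 19 cases (adjusted p = 1.93e-06; adjusted p of at least 0.97 with an estimated correlation), with Nup37 at -1.78 (SE 0.08) and Nup85 at -1.65 (SE 0.08). Splicing factors of the SR family fell in 7 of 10 cases (adjusted p = 0.00999, and adjusted p of at least 0.97 with an estimated correlation), Srsf6 most (-1.75, SE 0.08). Subunits of the RNA exosome fell in 8 of 10 cases (adjusted p = 0.0118, and adjusted p of at least 0.97 with an estimated correlation), Exosc8 most (-2.91, SE 0.08, but 0.17 at a second, dimmer probe set), but in 5 without DMSO 1, DMSO 2 or Vorinostat 2. With arrays scaled on the reference genes, the medians of these 3 families were -0.72, -0.61 and -0.49, and 14, 7 and 5 of their members fell and 2, 2 and 2 rose. That scaling can only raise a change, and the members that rose in the families above then numbered 12 for intraflagellar transport, 19 for Atp6, 16 for metalloproteinases and 15 for Krüppel-like factors. Genes with symbols starting with Rpl, a stem of ribosomal protein genes, fell in 6 of 24 cases and rose in 0 (camera adjusted p = 0.0118, and at least 0.97 with an estimated correlation). Those starting with Rps fell in 9 of 30 cases and rose in 2, and did not pass (camera adjusted p = 0.0518). The Rps stem is not limited to ribosomal protein genes: its largest change was that of the kinase gene Rps6ka5 (1.37). In 2 genes, probe sets changed by at least 2-fold in opposite directions, at 1.41 and -1.33 for Cpsf6 and 1.31 and -1.97 for Mtm1.

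Cd68, best known as a macrophage marker, rose 25.1-fold to a level of 9.26. Macrophages or other immune cells in the treated cultures would have brought their other transcripts along. The median change of 8 other myeloid markers, including Ptprc, Lyz2 and Csf1r, was -0.0841, with a 95% bootstrap interval of -0.18 to 0.08. In limma 0 of the 8 passed and 0 had an unadjusted p under 0.05, which argues against immune cells as the source. That the cancer cells themselves may raise this lysosomal gene with vorinostat remains a hypothesis without a test of its own.

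Most calls turned to higher when arrays were scaled on the reference genes. If the deposited normalization had hidden a rise of all transcripts that the reference genes did not share, bacterial spike-in controls, which no cell makes, could lie lower by about the shift of those genes. The median change of 29 spike-in probe sets was -0.0382, with a 95% bootstrap interval of -0.11 to 0.03, against a mean of -0.31 for the reference genes, or -0.09 without Gusb and Polr2a. How these controls were added is not known here. If they were added per amount of RNA or of labelled material, a rise of all transcripts in each cell would leave them flat as well. The spike-ins therefore cannot decide the question. The reference genes did not move alike: besides Gusb and Polr2a, the other 7 lay between -0.26 and 0.08. This argues against a shared shift of -0.31 in all 9 reference genes. A smaller rise of the other transcripts cannot be told apart from shifts of single reference genes.

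Neighbouring genes changed together slightly: over 18009 adjacent pairs, the Pearson correlation of log2 changes across genes, which are not independent replicates, was 0.0369 (Spearman 0.0346), above the highest of 1000 shuffled gene orders, 0.0222, which argues against a chance order. Without pairs whose symbols share the first 3 letters it was 0.0252, above the highest shuffled value of 0.0236. That met the criterion set beforehand, which was only to exceed every shuffled order. The excess was less than the standard error of 0.0078, a stricter condition that was not part of that criterion. By this stricter condition, transcripts or probes shared between neighbouring paralogs cannot be told apart from a regional response. Of 2990 such pairs with both genes past the threshold, 52.5% changed in the same direction, where 50.1% would be expected. The longest run of neighbours that each rose at least 2-fold held Zc2hc1a, Il7, Stmn2 and Hey1 on chromosome 3, with a median change of 1.19.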
